A study of Mus musculus with 13 samples.

How the data were processed

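RNA from 13 samples of primary cortical neurons (Swiss albino mouse, gestational days 15 to 16, day 5 of culture) was extracted with an RNeasy kit, amplified to biotin-labelled cRNA with an Ambion MessageAmp kit and hybridised to Illumina MouseRef-8 V1.1 arrays, per the labels' protocols. The groups were vehicle control (n = 4) and 10 nM rotenone for 8 h, 15 h and 24 h (n = 3 each). The probe signal table holds bead signal intensity per probe and array as the authors deposited it, not scaled between arrays. A gene profile made with BeadStudio 3.2.6 holds one signal intensity per gene and array with no normalization, per the file headers. Its detection score is a fraction, 1 less the detection p, per the file headers. The authors' normalized values, and the series matrix values, whose 24393 lines were all found among them, are a ratio, the signal over the array's median and then over the median of the controls. That was found by recomputing them, with a largest relative difference of 3.75e-07.

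The chosen design called for neqc, which needs a detection p beside each probe signal. The signal table has none, so the fallback written beforehand was used: normexp background correction (offset 50) and quantile normalization over all 13 arrays, on the log2 scale. Detection was read through the gene profile, by finding for each sample the profile array with identical signals (tolerance 0.05). For all 13 samples that array was another replicate of the same group than the array label names, so the groups are the same either way, but the chips differ. Both assignments of arrays to 2 chips were tried, called here the labels' chips and the matched chips. The profile holds 16 arrays, of which 3 belong to no sample here, and 102 of its per-array columns were not used.

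Of 24923 probes 24613 had a signal. Symbols were found for 20514 probes by RefSeq accession and for 2554 by the description, with 471 more whose symbol in the description is not in the reference, and 1074 had none. Where both sources gave a symbol they were the same for 18629 of 18731 probes (99.5%). The identifier column was not used, because of 7879 identifiers that could be followed 17 name the gene on their own line and 7746 one on a later line. Probes were kept where the detection p was under 0.05 on at least 3 arrays, which left 14345 probes, 13856 of them with a symbol. The brightest probe per gene gave 11048 genes, and 489 kept probes have no symbol.

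Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, 9 residual degrees of freedom) in one fit of all 4 groups, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. The comparisons were each time against control and each pair of times. A gene detected on no array of a group has only a bound there. Its fold is written as at least the bright group's mean over the dim group's mean, the latter taken per array as the higher of the lowest signal among detected probes and the probe's own. Of 28 fixed gene lists 27 had at least 4 measured members and were tested with camera (preset correlation 0.01), again with an estimated correlation, and with fry, adjusted over the lists. Each list's members were also adjusted over the list alone. The lists cover respiratory chain complexes, glycolysis, hypoxia, stress responses, cholesterol synthesis, p53 targets, cell death, immediate early genes, synapse, cytoskeleton, proteasome, lysosome, metal response, inflammation, Parkinson disease genes, cell cycle, ribosome and markers of 7 cell types. The glutamatergic and synapse lists share 2 members and the p53 list shares 5 with others.

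The design, the lists, the threshold and the rule for named genes were chosen before the data were examined. The rule names, against control, the 6 largest rises and the 6 largest falls among called genes whose treated arrays all lie on one side of all 4 controls. It adds the 2 called members with the smallest p of each list (4 for lists called by camera), and at every time a fixed set that includes Ddit3, Trib3, Atf3, Hmox1, Cdkn1a, Bbc3, Fos, Bdnf and Gfap. The results of some genes the rule names are not printed. Between times it names the 5 largest rises and falls. Correlations of log2 changes across genes were set beside 100 simulated draws of unchanged groups and beside controls split in pairs.

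The alternatives were no background correction (offset 16), median scaling, the authors' normalized values, no detection filter, a strict one (0.01), the mean of probes, the labels' chips as a block or singly, a replicate block, array weights, only the groups compared, and leaving out each array. Added after seeing the data were no scaling between arrays, neqc, and the matched chips as a block or singly. The pipeline was tested on simulated data for 24 h against control with 11048 genes. It called 57 of 67 genes changed 1.5-fold (85.1%), 67 of 67 changed 2-fold and 66 of 66 changed 4-fold, and 12 of 10828 unchanged genes (5.50% of calls). The median folds found were 1.48, 1.86 and 3.39, so the larger simulated folds came out smaller than they were set. None of the 100 unchanged lists was called, but their genes were simulated as independent, so this does not test lists whose genes vary together. The simulation changed few genes (200 seeded singly), with about as many raised as lowered and no fall in signal. It therefore does not test the scaling where as many genes change as at 15 h and 24 h. Tables were prepared with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The mean signal per group, 371 in controls and 235 at 24 h, stands over a 5th percentile of 37.4 and 33.7, which sets how small a change of a dim gene can be seen.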

Results

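Gene expression was measured on Illumina mouse bead arrays in 13 RNA samples from primary cortical neurons of fetal Swiss albino mice. The cells had been treated with 10 nM rotenone, an inhibitor of complex I of the mitochondrial respiratory chain, for 8 h, 15 h or 24 h (n = 3 each), or with vehicle (n = 4). The series asks which genes change as rotenone kills neurons, and the time points ask in what order they do so. The time at which the vehicle samples were taken is not given in the sources used here, so a change against control holds both the drug and any change of the cultures with time. Replicates are not said to come from separate cultures, so the p-values measure only the spread between these samples. The number of arrays limits the precision. Where a fixed list is given against control without a second count, its count adjusted over the list alone was the same.

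The mean probe signal was 371 ± 34.2 (SD) in controls and 363 ± 34.8 at 8 h, and then lower, at 270 ± 16.1 at 15 h and 235 ± 20.7 at 24 h. The share of probes detected stayed between 51.8% and 52.3% in the 4 groups. In a principal component analysis the first component held 73.5% of the variance and parted the controls and the 8 h samples from the 15 h and 24 h samples. The second component held 11.1% and parted 15 h from 24 h. Replicate 1 at 15 h stood apart from its group, at −31.3 on the second component against −10.9 and −10.3 for the other 15 h samples. On the first component it lay at 34.7 against 24.5 and 24.2, nearer the 24 h samples. Its mean correlation with its own group was 0.975, against 0.987 and 0.986 for the others, and its share of detected probes, 50.2%, was the lowest of the 13 arrays.

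**Figure D1:**
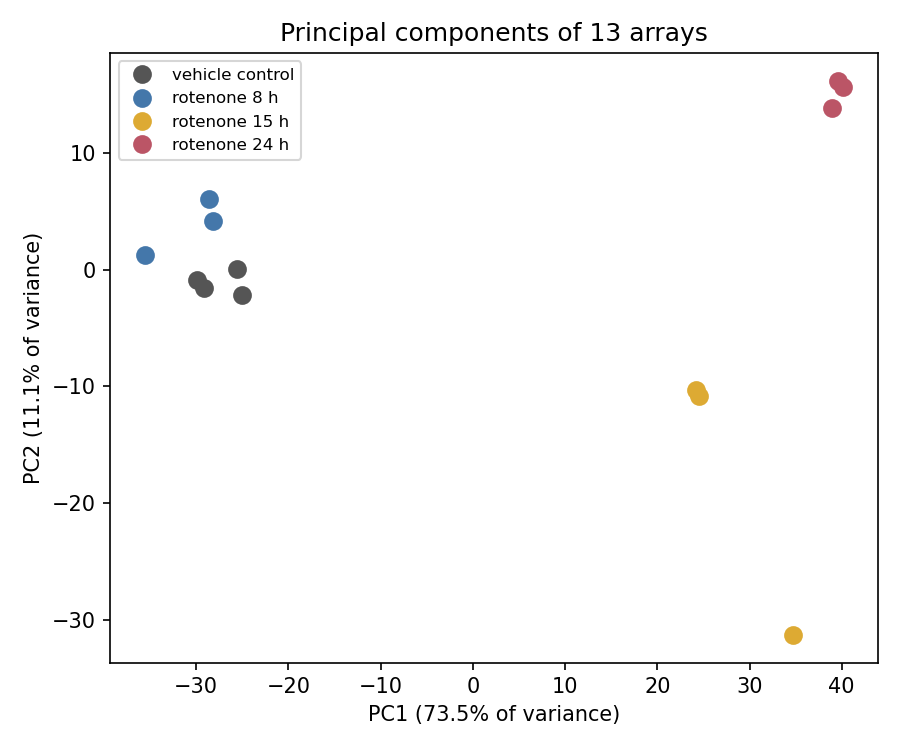
Positions of the 13 arrays on the first (73.5% of variance) and second (11.1%) principal components of the normalised log2 values of all genes tested, coloured by group. Controls and 8 h samples lie together on the left, 15 h and 24 h samples on the right, and 15 h replicate 1 lies lowest, at −31.3 on the second component.

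After 8 h of rotenone, the comparison with control asks what changed first. Genes of cholesterol synthesis rose together, and a few markers of GABAergic neurons and of the oligodendrocyte lineage fell. Insig1, which holds the sterol-sensing complex in the endoplasmic reticulum, rose 2.25-fold (log2 change 1.17 ± 0.14, adjusted p = 0.0011; here and below ± is the standard error of the fit). The neuropeptide gene Sst fell by 1.29 ± 0.13 on the log2 scale (adjusted p = 2.7e-04), and Angptl4, a secreted inhibitor of lipoprotein lipase, fell by 1.52 ± 0.22 (adjusted p = 0.0047), with its second probe at −0.28. Each of these changes held for all 3 treated samples against all 4 controls.

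Of 21 measured cholesterol synthesis genes 10 were higher and 0 lower at 8 h (17 and 0 adjusted over the list alone), with a median log2 change of 0.61. The enzymes Lss (1.04 ± 0.14), Msmo1 (1.00 ± 0.14) and Cyp51 (0.84 ± 0.11) form or modify the sterol ring, and Stard4 (0.82 ± 0.10) carries sterol between membranes. Tested with camera, this list stood above other genes with an adjusted p = 6.6e-28, and with p = 0.0015 with an estimated correlation. Among 9 measured GABAergic markers 2 were lower, Sst and the interneuron transcription factor Dlx2 (−0.59 ± 0.09), and 7 were lower with 1 higher when adjusted over the list alone. The median was −0.50 (camera adjusted p = 2.3e-07, and p = 0.0036 with an estimated correlation). Dlx2 lost its call without 8 h replicate 3 (−0.55) and with no scaling (−0.63), and its second probe was at −0.22. Of 11 oligodendrocyte lineage markers 1 passed, Gpr17, a receptor of precursor cells (−1.19 ± 0.22), and 7 were lower when adjusted over the list alone. Their median was −0.46 (camera adjusted p = 1.1e-07, and p = 0.042 with an estimated correlation). Gpr17 lost its call without control replicates 1 (−1.13), 2 (−1.19) or 4 (−1.06), or without 8 h replicates 1 (−1.14) or 3 (−1.07).

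The other 6 lists that camera called at 8 h moved little, and none of these calls held with an estimated correlation. Of these lists only the complex I subunits were also called by fry, as lower. Some lists not called at 8 h gained a camera call when 1 array was left out. Metal response genes were lower without control replicates 1 (adjusted p = 0.0399) or 2 (0.0077) or 8 h replicates 1 (0.0121) or 3 (0.0078). Immediate early and cell cycle genes were higher without control replicate 3 (0.0041 and 0.0040). The p53, fibroblast and lysosome lists also gained calls in this way. Integrated stress response genes had a median of 0.18, or 0.15 with members at a detection bound set to it (adjusted p = 2.9e-07, and p = 0.264 with an estimated correlation). None of the 36 passed by limma, over all genes or adjusted over the list alone, while 9 were higher and 0 lower at an unadjusted p under 0.05. Cytoskeleton and axon genes had a median of 0.17 (adjusted p = 7.5e-05, and p = 0.197 with an estimated correlation). Of these 32 none passed by limma over all genes, 1 was higher adjusted over the list alone, and 11 were higher and 1 lower at an unadjusted p under 0.05. Complex I subunits, the target of the drug, had a median of −0.10 (adjusted p = 1.7e-04, and p = 0.197 with an estimated correlation). Genes of complexes II to V had a median of −0.12 (adjusted p = 0.0032, and p = 0.284 with an estimated correlation). By limma no gene of either respiratory list passed over all genes or adjusted over the list alone, with 6 of 31 and 2 of 36 lower and 0 higher at an unadjusted p under 0.05. For 7 of the 9 called lists the estimated correlation gave the highest adjusted p of the 31 camera alternatives. The call on complexes II to V was also lost under median scaling (adjusted p = 0.071), the authors' values (0.204), no scaling (0.152) and within matched chip 1 (0.102), in a range from 1.7e-04 to 0.284 over its alternatives, and that on the integrated stress response within matched chip 1 (0.143), in a range from 4.8e-14 to 0.264.

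NRF2 targets, genes of antioxidant defence, had a median of −0.13 at 8 h (adjusted p = 1.2e-04, and p = 0.197 with an estimated correlation). Of 29 members 2 were lower, Gsta4 (−0.93 ± 0.16) and Ephx1 (−0.80 ± 0.17), and 4 adjusted over the list alone. Gsta4 lost its call without control replicates 1 (−0.93) or 2 (−0.95) or 8 h replicates 1 (−0.92) or 3 (−0.96). Ephx1 lost it when any one of 11 arrays was left out, that is each except control replicate 3 and 15 h replicate 1, with values from −0.90 to −0.66. The Ephx1 call was also lost under median scaling (−0.83), in the authors' values (−0.86) and with no detection filter (−0.80). The same held with the labels' chips (−0.77) or the replicates (−0.66) as a block and with only the groups compared (−0.80). The NRF2 call was lost with array weights (adjusted p = 0.0819) and within matched chip 2 (0.2000), in a range from 1.2e-06 to 0.2000 over its alternatives. Astrocyte markers had a median of −0.11 (adjusted p = 0.0052, and p = 0.197 with an estimated correlation). Of 18 members 1 was lower, the glial transcription factor Sox9 (−0.71 ± 0.11), and 3 adjusted over the list alone. Sox9 lost its call without 8 h replicates 1 (−0.67) or 3 (−0.58). The list lost its call without 8 h replicate 2 (adjusted p = 0.278), with array weights (0.205) and within chip 2 (0.410) and matched chip 2 (0.201), in a range from 1.6e-04 to 0.41 over its alternatives.

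Genes of stress and cell death named in advance did not pass at 8 h. Hmox1, heme oxygenase, stood at −0.13 ± 0.26 (adjusted p = 0.92), and Ddit3, which encodes the stress transcription factor CHOP, at 0.25 ± 0.22 (adjusted p = 0.75). The p53 target Cdkn1a was at −0.59 ± 0.16 (adjusted p = 0.13), and Bbc3 at −0.05 and Gfap at −0.13 were likewise not called. The stress transcription factor Atf3 was at 0.38 ± 0.17 (adjusted p = 0.43) and Fos at 1.19 ± 0.62 (adjusted p = 0.52). Both passed without 8 h replicate 2, at 0.67 and 2.20. With array weights, where many more genes were called, Ddit3 (0.61), Cdkn1a (−0.50), Atf3 (0.64) and Fos (2.26) passed. Cdkn1a also passed with the mean of probes (−0.64). Trib3 was detected on no control or 8 h array, so it has no fold at 8 h. Bdnf was detected on too few arrays to be tested.

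In all, limma called 48 of 11048 genes at 8 h, 16 higher and 32 lower, of which 13 and 22 changed at least 1.5-fold, and 1180 genes had an unadjusted p under 0.05. The split was 10 higher and 47 lower with no scaling between arrays. The count of 48 depended on single arrays. It became 16, 17, 129 and 19 without control replicates 1, 2, 3 and 4 in turn, and 10, 179 and 10 without 8 h replicates 1, 2 and 3. It became 184 without 15 h replicate 1, and 26, 25 and 28 without 24 h replicates 1, 2 and 3, which enter only through the shared spread. Within chips it was 3 on chip 1 and 0 on chip 2 (limma, 856 genes at an unadjusted p under 0.05) as the labels assign them, and 3 and 1458 as identical signals assign them. Each chip 2 holds a single 8 h array, assumed to vary like the others. With chip as a block it was 37 by the labels and 50 by identical signals. Insig1, Lss, Msmo1, Cyp51, Stard4, Sst and Angptl4 kept their calls whichever array was left out. They lost them within each of the labels' chips, where Insig1 was at 1.15 on both and Sst at −1.19 and −1.41.

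**Figure D2:**
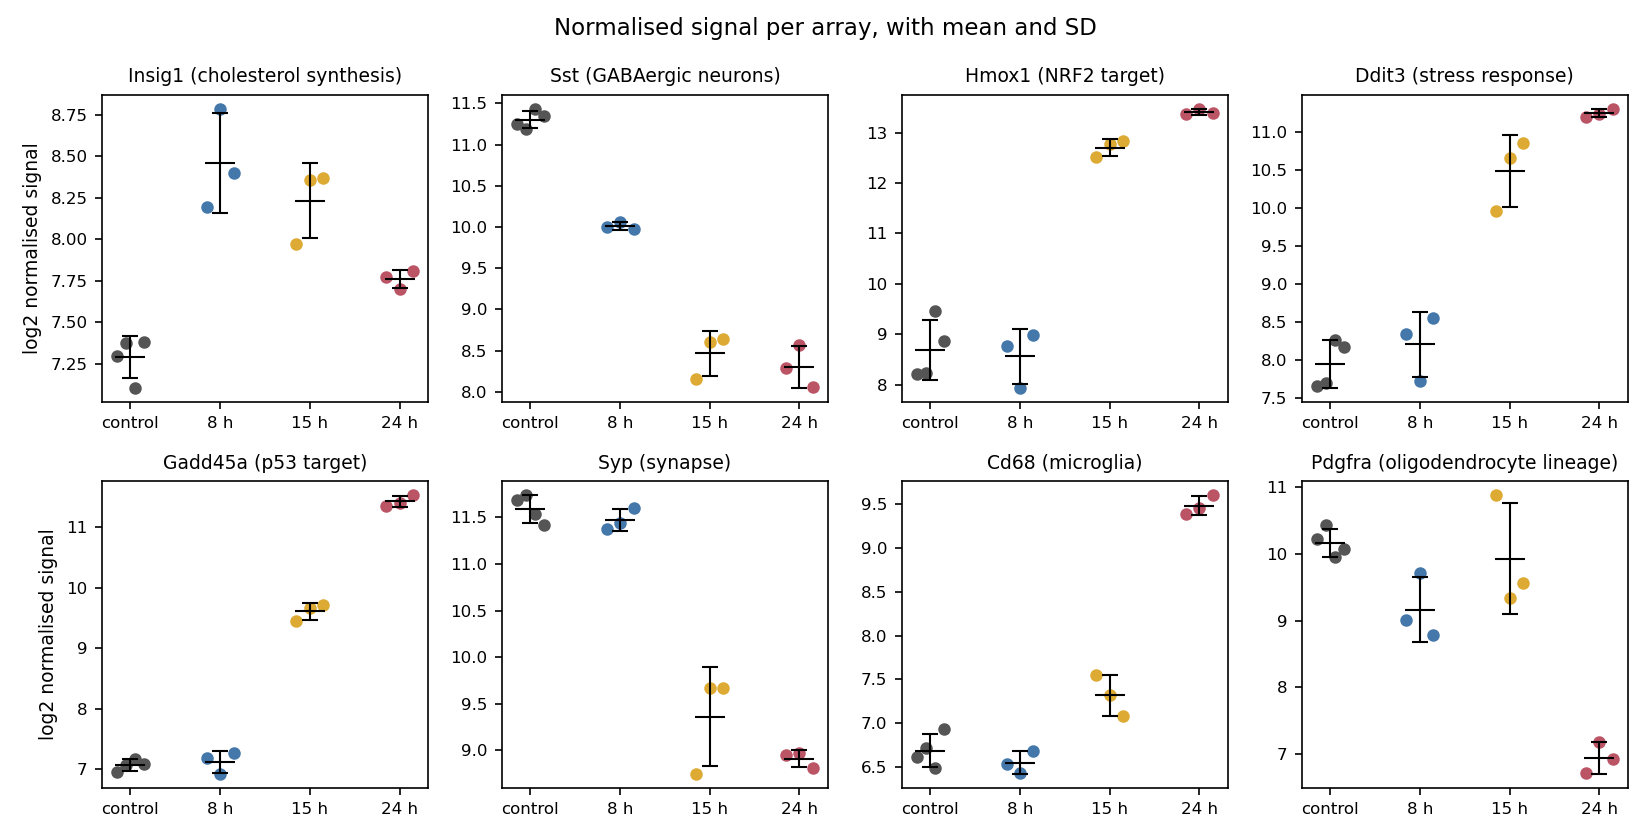
Normalised log2 values of 8 named genes on each array by group (control, 8 h, 15 h, 24 h), with the group mean and SD. Insig1 is higher at 8 h (1.17), Sst lower from 8 h on (−3.00 at 24 h), Hmox1 (4.72), Ddit3 (3.31) and Gadd45a (4.36) higher at 24 h, Syp lower at 15 h (−2.23), Cd68 higher (2.79) and Pdgfra lower (−3.24) at 24 h.

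At 15 h, the comparison with control asks what had changed once the response was broad. By camera NRF2 targets and integrated stress response genes were higher and genes of synapses and axons lower, although no list call at 15 h held with an estimated correlation (lowest adjusted p = 0.0508). Hmox1 rose 16.1-fold (4.01 ± 0.26, adjusted p = 1.4e-08), and Nupr1, a stress-induced chromatin protein, rose by 3.58 ± 0.14 (adjusted p = 1.4e-10). Gdf15, a stress cytokine detected on no control array, was at least 9.16-fold higher (adjusted p = 2.2e-09). Sst fell by 2.84 ± 0.13 (adjusted p = 9.5e-10), the synuclein gene Sncb fell by 2.44 ± 0.17 (adjusted p = 2.1e-08) and the synaptic vesicle gene Syp fell by 2.23 ± 0.17 (adjusted p = 6.8e-08). Srxn1, which repairs oxidised peroxiredoxins, and the glucose transporter gene Slc2a1 rose by 2.89 ± 0.25 and 2.73 ± 0.24.

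Of 29 NRF2 targets 23 were higher and 1 lower (24 and 1 adjusted over the list alone), with a median of 0.89. They included the glutathione synthesis gene Gclm (2.13 ± 0.13), the cystine transporter gene Slc7a11 (2.46 ± 0.14) and Me1 (1.35 ± 0.11). The camera adjusted p was 9.5e-11, and p = 0.0508 with an estimated correlation. Of 36 integrated stress response genes 25 were higher and 1 lower, the same adjusted over the list alone, with a median of 0.85, or 0.75 with members at their bound. Ddit3 rose by 2.55 ± 0.22 and Atf3 by 1.66 ± 0.17, while Trib3 was at least 3.29-fold higher. By camera the adjusted p was 9.0e-08, and p = 0.193 with an estimated correlation. Of 22 p53 targets 12 were higher and 2 lower (12 and 4 adjusted over the list alone), with a median of 0.36. Gadd45a, a growth arrest gene, rose by 2.54 ± 0.11, the death receptor gene Fas by 0.82 ± 0.09 and Cdkn1a by 0.69 ± 0.16 (its second probe 0.18), while Plk2 fell by 0.97 ± 0.11. Cdkn1a lost its call under median scaling (0.19), the authors' values (0.22) and no scaling (0.098). Tested with camera, the list had an adjusted p = 0.0102, and p = 0.0597 with an estimated correlation. The brightest probe of Ccng1, a further called member, rose by 1.995 ± 0.10, and its other probes were at 1.88 and 0.11.

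All 4 metal response genes were higher (4 also adjusted over the list alone), with a median of 0.81. Under median scaling, the authors' values and no scaling 2 were called, as Slc30a1 (0.21, 0.25 and 0.12) and Mt3 (0.064, 0.090 and −0.026) lost their calls. The metallothionein genes Mt2 and Mt1 rose by 1.62 ± 0.14 and 1.02 ± 0.10 (camera adjusted p = 0.0104, and p = 0.193 with an estimated correlation). The heat shock list was not called by camera at 15 h but was higher by fry (adjusted p = 3.5e-05), and Hspb8 (2.60 ± 0.15) and the mitochondrial chaperone gene Hspa9 (1.52 ± 0.13) rose; 8 of 17 members were higher and 4 lower (9 and 5 adjusted over the list alone).

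Of 32 synapse genes 28 were lower and 2 higher (29 and 2 adjusted over the list alone), with a median of −1.14. Stx1a, a protein of vesicle fusion, fell by 1.61 ± 0.10, and so did the synapsin gene Syn1 (−2.04 ± 0.13) and the kinase gene Camk2b (−1.88 ± 0.13). The camera adjusted p was 6.4e-13, and p = 0.0508 with an estimated correlation. Of 32 cytoskeleton and axon genes 23 were lower and 2 higher (23 and 3 adjusted over the list alone), with a median of −0.89. The tubulin gene Tubb4a (−2.18 ± 0.12) and Crmp1, a growth cone protein (−1.83 ± 0.14), fell, while Tubb6, a tubulin not restricted to neurons, rose by 2.31 ± 0.17. By camera the adjusted p was 9.0e-08, and p = 0.0857 with an estimated correlation. Glutamatergic markers were lower in 11 of 15 and higher in 1, the same adjusted over the list alone, with a median of −0.36 (camera adjusted p = 4.7e-04, and p = 0.0508 with an estimated correlation). They included the vesicular transporter genes Slc17a6 (−1.99 ± 0.14) and Slc17a7 (−1.36 ± 0.13) and the cortical transcription factor gene Tbr1 (−1.40 ± 0.12). GABAergic markers were lower in 5 of 9 and higher in 1 (5 and 2 adjusted over the list alone), with a median of −0.70 (camera adjusted p = 0.0277, and p = 0.102 with an estimated correlation). Calb2 (−1.24 ± 0.09) and Slc32a1, the vesicular transporter of inhibitory neurons (−1.59 ± 0.12), fell. The GABAergic call was lost in the authors' values (adjusted p = 0.0523) and within matched chip 2 (0.0872), in a range from 0.0107 to 0.102 over its alternatives. Dlx2, lower at 8 h, was higher here (0.73 ± 0.09), though its second probe was at −0.05 and the call was lost under median scaling (0.22) and no scaling (0.13).

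Markers of other cells moved at 15 h as well. Astrocyte markers were higher in 13 of 18 and lower in 0 (14 and 0 adjusted over the list alone), with a median of 0.60 (camera adjusted p = 4.7e-04, and p = 0.0857 with an estimated correlation). The glutamate transporter gene Slc1a3 rose by 1.14 ± 0.13 and Sox9 by 0.77 ± 0.11, a call on Sox9 that was lost under median scaling (0.26) and no scaling (0.17), while Gfap did not pass (0.07 ± 0.18). Microglia markers were higher in 5 of 11 and lower in 0, the same adjusted over the list alone, with a median of 0.22, or 0.11 with members at their bound (camera adjusted p = 0.0284, and p = 0.193 with an estimated correlation). They included Laptm5 (1.40 ± 0.16) and the lysozyme gene Lyz2 (0.97 ± 0.11). The microglia call was lost with no detection filter (adjusted p = 0.151) and within matched chip 2 (0.0587), in a range from 0.0022 to 0.193 over its alternatives. Fibroblast markers were higher in 5 of 8 and lower in 1, with a median of 0.44, or 0.38 with bounds (camera adjusted p = 0.0418, and p = 0.258 with an estimated correlation). The smooth muscle actin gene Acta2 rose by 2.37 ± 0.22 and fibronectin, Fn1, by 0.87 ± 0.12, with its other probes at 0.07 and 0.27. The fibroblast call was lost without control replicates 3 (adjusted p = 0.0531) or 4 (0.0523) or 15 h replicates 1 (0.0554) or 3 (0.0616), with no detection filter (0.0588), the strict filter (0.0527), the mean of probes (0.0554), a replicate block (0.0524) and array weights (0.0648), and within chip 1 (0.0648) and matched chip 2 (0.0962), in a range from 0.0046 to 0.258 over its alternatives. Oligodendrocyte lineage markers were not called, with 1 of 11 higher and 2 lower (1 and 0 adjusted over the list alone).

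Genes of the inflammation list were higher in 8 of 16 and lower in 0, with a median of 0.23, or 0.21 with bounds. The adhesion gene Vcam1 rose by 1.41 ± 0.19 and the cytokine signalling inhibitor Socs3 by 0.74 ± 0.13. Its camera adjusted p was 0.0277, and p = 0.258 with an estimated correlation. This call was lost without 15 h replicate 1 (adjusted p = 0.0573) and with array weights (0.0660), in a range from 8.5e-04 to 0.258 over its alternatives. Autophagy and lysosome genes were higher in 14 of 26 and lower in 4, with a median of 0.39 that became −0.09 with no scaling, or 0.17 relative to all genes. The lysosomal membrane gene Lamp2 rose by 1.43 ± 0.11 and the cathepsin gene Ctsb by 0.86 ± 0.08 (camera adjusted p = 0.0274, and p = 0.254 with an estimated correlation). This call was lost under median scaling (adjusted p = 0.239), the authors' values (0.153) and no scaling (0.153), within chip 1 (0.0759) and matched chip 2 (0.252), and without 15 h replicate 3 (0.0580), in a range from 0.0049 to 0.254 over its alternatives. Cell cycle genes were higher in 13 of 23 and lower in 1 (15 and 1 adjusted over the list alone), with a median of 0.49 that became −0.01 with no scaling, or 0.24 relative to all genes (camera adjusted p = 0.0011, and p = 0.309 with an estimated correlation). Cdc20 rose by 1.29 ± 0.17 and the replication gene Mcm2 by 0.85 ± 0.11, a call on Mcm2 that was lost with no scaling (0.38). Ribosomal protein genes were higher in 35 of 70 and lower in 2, with a median of 0.21 that turned to −0.01 under median scaling and −0.10 with no scaling, or 0.15 relative to all genes in both (camera adjusted p = 3.4e-04, and p = 0.0597 with an estimated correlation).

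At 15 h Fos (1.00 ± 0.62) did not pass but did without control replicate 3 (1.56), and Bbc3 (0.17 ± 0.08) did not pass but did without control replicate 1 (0.22) or 15 h replicate 1 (0.25).

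At 15 h limma called 5541 genes, 2812 higher and 2729 lower, of which 1214 and 1313 changed at least 1.5-fold. Within chips the count was 3626 and 2541 by the labels and 3517 and 6730 by identical signals. With an estimated correlation 0 of the 15 camera calls held, the lowest adjusted p being 0.0508, while 20 lists passed by fry. The estimated correlation gave the highest adjusted p of the 31 camera alternatives for 14 of the 15 called lists, the p53 targets reaching 0.106 within matched chip 2.

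At 24 h, the comparison with control asks how far the response had gone. By camera NRF2 and p53 targets were higher and synapse, GABAergic and glutamatergic lists lower, also with an estimated correlation. Integrated stress response, heat shock and metal response genes were called higher by camera with the preset correlation but not with an estimated one. The unfolded protein response was not called. Hmox1 rose by 4.72 ± 0.26 (adjusted p = 7.4e-10), Gadd45a by 4.36 ± 0.11 (adjusted p = 1.5e-13) and the glutathione transferase gene Gsta2 by 4.20 ± 0.10 (adjusted p = 7.1e-14). Gdf15 was at least 19.1-fold higher (adjusted p = 3.0e-11). Tnfrsf12a, a receptor of the TNF family, and Anxa3 rose by 4.69 ± 0.24 and 4.67 ± 0.14. The synaptic calcium sensor gene Syt1 (−3.36 ± 0.23), Slc17a6 (−3.08 ± 0.14) and Pdgfra, a receptor of oligodendrocyte precursors (−3.24 ± 0.29), fell.

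Of 29 NRF2 targets 25 were higher and 0 lower, the same adjusted over the list alone, with a median of 1.32 (camera adjusted p = 2.5e-12, and p = 0.0264 with an estimated correlation). Gclm rose by 2.91 ± 0.13 and Gsta1 was at least 6.99-fold higher. Of 36 integrated stress response genes 29 were higher and 0 lower (30 and 0 adjusted over the list alone), with a median of 1.18 (camera adjusted p = 3.1e-12, and p = 0.0852 with an estimated correlation). Ddit3 rose by 3.31 ± 0.22, Atf3 by 3.10 ± 0.17 and Nupr1 by 3.86 ± 0.14, and Trib3 was at least 4.44-fold higher. Of 22 p53 targets 14 were higher and 2 lower, with a median of 0.58 (camera adjusted p = 0.0011, and p = 0.0264 with an estimated correlation). Cdkn1a rose by 1.09 ± 0.16, a call lost with no scaling (0.26), Fas by 1.37 ± 0.09 and Mdm2, the ubiquitin ligase for p53, by 1.23 ± 0.12. Of 17 heat shock genes 9 were higher and 3 lower, with a median of 0.42 (camera adjusted p = 0.0108, and p = 0.0918 with an estimated correlation). The small heat shock protein genes Hspb1, Hspb8 and Cryab rose by 1.91 ± 0.08, 3.41 ± 0.15 and 1.87 ± 0.14. All 4 metal response genes were higher, or 3 with no scaling, with a median of 1.27 (camera adjusted p = 0.0029, and p = 0.111 with an estimated correlation). Bbc3 did not pass (0.07 ± 0.08).

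Of 32 synapse genes 30 were lower and 1 higher (30 and 2 adjusted over the list alone), with a median of −1.34 (camera adjusted p = 2.1e-13, and p = 0.0264 with an estimated correlation). The vesicle genes Rab3a (−1.59 ± 0.09) and Cplx1 (−1.48 ± 0.09) fell. Of 9 GABAergic markers 8 were lower and 0 higher (8 and 1 adjusted over the list alone), with a median of −1.72 (camera adjusted p = 6.3e-06, and p = 0.0185 with an estimated correlation). Sst (−3.00 ± 0.13), Slc32a1 (−2.68 ± 0.12), Dlx1 (−1.93 ± 0.11) and Dlx2 (−1.89 ± 0.09) fell, with the second probe of Dlx2 at −0.52. Glutamatergic markers were lower in 9 of 15 and higher in 0, with a median of −0.29 (camera adjusted p = 5.5e-04, and p = 0.0295 with an estimated correlation). Tbr1 (−1.56 ± 0.12) and Slc17a7 (−1.54 ± 0.13) fell. Cytoskeleton and axon genes were lower in 24 of 32 and higher in 2, with a median of −0.86 (camera adjusted p = 2.1e-07, and p = 0.0748 with an estimated correlation). The kinesin gene Kif5c (−1.86 ± 0.12) and the tubulin gene Tubb4a (−1.81 ± 0.12) fell.

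Markers of other cell types parted at 24 h. Microglia markers were higher in 9 of 11 and lower in 0, with a median of 0.62 (camera adjusted p = 5.0e-04, and p = 0.0454 with an estimated correlation). The lysosomal gene Cd68 rose by 2.79 ± 0.13, Laptm5 by 2.02 ± 0.16 and Tyrobp by 0.78 ± 0.08. Oligodendrocyte lineage markers were lower in 7 of 11 and higher in 2, with a median of −0.60, or −0.37 with bounds (camera adjusted p = 0.0140, and p = 0.219 with an estimated correlation). The lineage transcription factors Olig1 (−1.37 ± 0.12), Olig2 (−0.89 ± 0.11) and Sox10 (−2.02 ± 0.26) were among them. The call was lost in the authors' values (adjusted p = 0.0523) and within chip 1 (0.0595), in a range from 0.0021 to 0.219 over its alternatives. Fibroblast markers were higher in 6 of 8 and lower in 1, with a median of 0.93, or 0.79 with bounds (camera adjusted p = 0.0066, and p = 0.111 with an estimated correlation). Acta2 rose by 3.53 ± 0.22 and Fn1 by 1.89 ± 0.12, with the other probes of Fn1 at 0.55 and 0.81. Astrocyte markers were higher in 10 of 18 and lower in 3, with a median of 0.55 (camera adjusted p = 0.0420, and p = 0.248 with an estimated correlation). Clu, a secreted chaperone, rose by 1.48 ± 0.18 and Gfap by 0.85 ± 0.18, while Sox9 fell by 0.92 ± 0.11. Gfap lost its call under median scaling (0.38), the authors' values (0.50), no scaling (0.25), within chip 2 (0.62) and within matched chip 1 (0.79). The astrocyte call was lost without control replicate 3 (adjusted p = 0.0624) or 24 h replicates 1 (0.0558) or 2 (0.0546) and with the strict detection filter (0.0514), in a range from 0.0070 to 0.248 over its alternatives. Of the endothelial markers 3 were measured, too few for the list test, with a median of −0.047 relative to all genes, and Flt1 was higher (0.76 ± 0.07).

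Inflammation genes were higher in 11 of 16 and lower in 0 at 24 h, with a median of 0.46, or 0.40 with bounds (camera adjusted p = 2.5e-04, and p = 0.0782 with an estimated correlation). The chemokine gene Cxcl1 rose by 2.35 ± 0.12 and the interferon-induced gene Isg15 by 1.12 ± 0.08. Autophagy and lysosome genes were higher in 15 of 26 and lower in 5, or 9 and 11 under median scaling, with a median of 0.57 (camera adjusted p = 0.0029, and p = 0.111 with an estimated correlation). The call was lost under median scaling (adjusted p = 0.0517), in a range from 0.0012 to 0.111 over its alternatives. Ctsb, Ctsd and Lamp2 rose by 1.40 ± 0.08, 1.48 ± 0.12 and 1.64 ± 0.11. Cell cycle genes were higher in 16 of 23 and lower in 1 (17 and 1 adjusted over the list alone), with a median of 0.46 that turned to −0.06 under median scaling and −0.19 with no scaling, or 0.20 relative to all genes in both (camera adjusted p = 0.0011, and p = 0.266 with an estimated correlation). Ccnd1, cyclin D1, rose by 1.44 ± 0.11 and Cdk1 by 1.19 ± 0.14. Ribosomal protein genes were higher in 39 of 70 and lower in 1 (42 and 1 adjusted over the list alone), with a median of 0.24 that turned to −0.10 under median scaling, where 1 was higher and 8 lower, and to −0.24 with no scaling, where 0 were higher and 21 lower. Relative to all genes it was 0.15 under both. The camera adjusted p was 1.8e-05, with p = 0.0276 with an estimated correlation, but 0.168 under median scaling and 0.174 with no scaling, in a range from 6.4e-08 to 0.174 over its alternatives. Fos rose by 1.75 ± 0.62 (adjusted p = 0.025), a call lost without control replicates 1 (1.62), 2 (1.61) or 4 (1.44) or 24 h replicates 1 (1.72), 2 (1.76) or 3 (1.75), under median scaling (1.18), the authors' values (1.37) and no scaling (1.04), and within chips 1 (2.18) and 2 (1.33) and matched chip 1 (1.34).

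**Figure D3:**
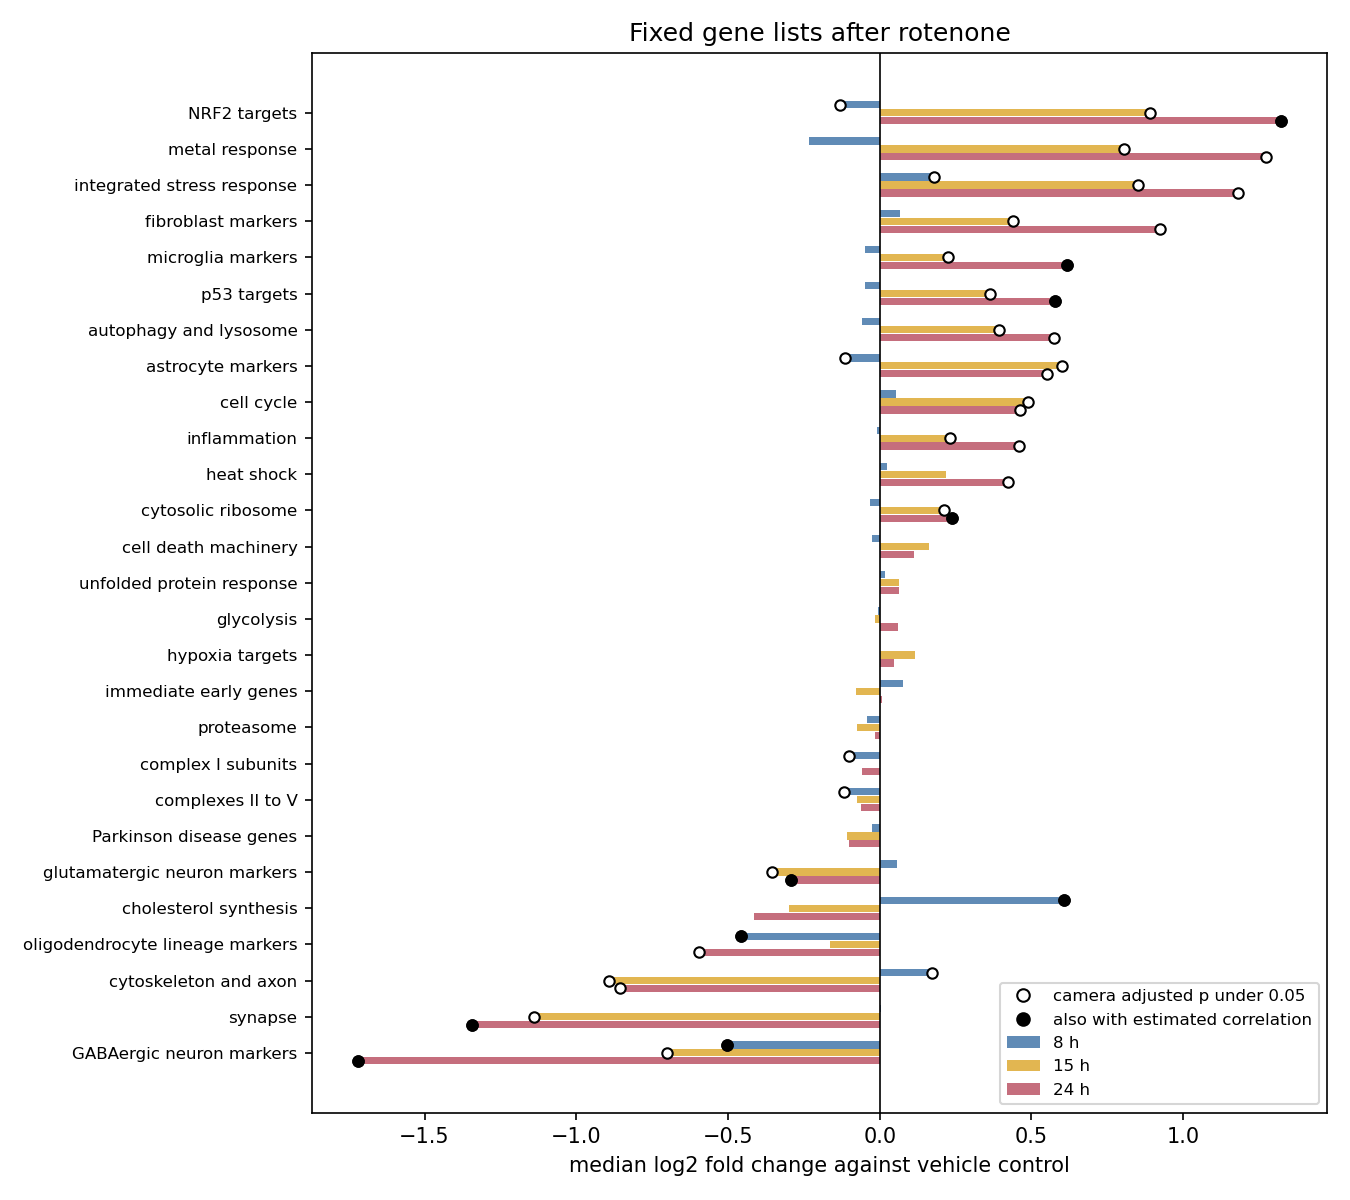
Median log2 change against control of each gene list at 8 h, 15 h and 24 h in the quantile-normalised data (bars), with open circles where the camera adjusted p passed and filled circles where it also passed with an estimated correlation. Synapse genes reach −1.34 and NRF2 targets 1.32 at 24 h, while the small rise of ribosomal protein genes (0.24) and the rise of cell cycle genes (0.46) turn to −0.24 and −0.19 with no scaling between arrays, where the median of all genes is −0.39.

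Several lists were not called by camera at 15 h or 24 h in the quantile-normalised data, and some of these were called under another scaling or by fry, which compares with no other genes. Complex I subunits were 6 higher and 4 lower of 31 at 15 h and 3 and 7 at 24 h (3 and 5 adjusted over the list alone), where Ndufv3 fell by 0.93 ± 0.11. Its second probe was at −0.10. The 15 h median (−0.00) and mean (0.02) of this list differed in sign. Under median scaling the list was lower in 18 and higher in 0 at 15 h, with a median of −0.41, and lower in 23 and higher in 0 at 24 h, with −0.68. Relative to the median of all genes those were −0.25 and −0.43. At 24 h camera then called the list lower, with an adjusted p of 0.0093 under median scaling, 0.0150 in the authors' values and 0.0204 with no scaling, in a range from 0.0093 to 0.888 over its alternatives. Genes of complexes II to V were 3 higher and 6 lower of 36 at 24 h (1 and 4 adjusted over the list alone), but 0 and 30 under median scaling, with −0.60, or −0.34 relative to all genes. At 15 h they were 5 higher and 6 lower (4 and 6 adjusted over the list alone). Camera called them lower at 24 h under median scaling (adjusted p = 0.0039), in the authors' values (0.01001) and with no scaling (0.0129), in a range from 0.0039 to 0.76, and at 15 h under median scaling (0.0265) and in the authors' values (0.0336), in a range from 0.0265 to 0.995. Glycolysis genes were 8 higher and 6 lower of 21 at 24 h, where hexokinase 2, Hk2, rose by 3.37 ± 0.14 and the regulator Pfkfb3 by 1.47 ± 0.09, and the median of 0.06 turned to −0.55 under median scaling, or −0.30 relative to all genes. At 15 h they were 6 higher and 7 lower (6 and 8 adjusted over the list alone), with a median of −0.02 and a mean of 0.03. By fry the glycolysis list was higher at 24 h (adjusted p = 2.8e-04).

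Hypoxia targets were 8 higher and 4 lower of 19 at 15 h and at 24 h, with medians of 0.12 and 0.05 that became −0.07 and −0.23 with no scaling, or 0.18 and 0.16 relative to all genes. With no scaling camera called them higher than other genes at 24 h (adjusted p = 0.0306), in a range from 0.0306 to 0.248 over the alternatives, and fry called them higher at 15 h and 24 h (4.3e-04 and 1.9e-05). Slc2a1 rose by 3.77 ± 0.24 at 24 h and the peptide gene Adm was at least 2.12-fold higher. Unfolded protein response genes were 4 and 4 of 18 at 15 h and 5 and 4 at 24 h, with Xbp1, its transcription factor, lower by −0.88 ± 0.14 at 24 h. Their median of 0.06 at 24 h turned to −0.27 under median scaling, or −0.02 relative to all genes. Cell death genes were 12 higher and 7 lower of 30 at 15 h and 10 and 7 at 24 h (11 and 7 adjusted over the list alone), with medians of 0.16 and 0.11 that turned to −0.14 and −0.37 under median scaling, or 0.03 and −0.12 relative to all genes. Fry called this list higher at 15 h (adjusted p = 0.012). At 24 h Bok, of the BCL2 family, fell by 1.39 ± 0.09. The calpain gene Capn2 rose by 0.91 ± 0.09 but lost its call under median scaling (0.19), the authors' values (0.30) and no scaling (0.059). Immediate early genes were 3 higher and 5 lower of 18 at 15 h and 6 and 3 at 24 h, with Homer1 lower by −0.89 ± 0.09 at 24 h. The 24 h median of these genes turned from 0.01 to −0.18 under median scaling, or 0.07 relative to all genes. Proteasome genes were 5 higher and 1 lower of 29 at 24 h (2 and 0 adjusted over the list alone), but 1 and 21 under median scaling, and 2 and 1 at 15 h (1 and 0 adjusted over the list alone). At 15 h camera called them lower under median scaling and in the authors' values (adjusted p = 0.0336 in both), in a range from 0.0336 to 0.995. Parkinson disease genes were 2 higher and 4 lower of 11 at 15 h and at 24 h, where Dnajc6, which uncoats clathrin vesicles, fell by 2.28 ± 0.23. Fry called this list lower at both times (adjusted p = 5.2e-04 and 0.0013), and camera did at 15 h within matched chip 2 (0.0348), in a range from 0.0348 to 0.386 over its alternatives. Cholesterol synthesis genes, higher at 8 h, were 2 higher and 9 lower at 15 h and 3 and 10 at 24 h, with medians of −0.30 and −0.41, or −0.16 and −0.21 with bounds. Insig1 was still higher at 15 h (0.94 ± 0.14). Camera called the cholesterol list lower at 15 h and 24 h under median scaling (adjusted p = 0.0304 and 0.0312), in the authors' values (0.0336 and 0.0333), with no scaling (0.0472 and 0.0383) and within matched chip 2 (0.0401 and 0.0458), as did fry (0.0025 and 5.9e-04). It also passed without 15 h replicate 2 at 15 h (0.0459), and at 24 h without 15 h replicate 1 (0.0443) and without a detection filter (0.0264). Its camera range was 0.0304 to 0.373 at 15 h and 0.0264 to 0.352 at 24 h.

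At 24 h limma called 6049 genes, 3028 higher and 3021 lower, of which 1408 and 1467 changed at least 1.5-fold. Within chips the count was 3063 and 4703 by the labels and 3709 and 6988 by identical signals. With an estimated correlation 7 of the 17 camera calls held, and 21 lists passed by fry. The estimated correlation gave the highest adjusted p of the 31 camera alternatives for 16 of the 17 called lists.

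The comparisons between time points test the order of events directly. From 8 h to 15 h limma called 5650 genes, 2854 higher and 2796 lower. Hmox1 rose by 4.14 ± 0.28 and Angptl4, low at 8 h, by 3.43 ± 0.24, while Sncb (−2.59 ± 0.18) and Crmp1 (−2.41 ± 0.15) fell. Cholesterol synthesis genes fell in 16 of 21 and rose in 0 (17 and 0 adjusted over the list alone), with a median of −0.79 (camera with an estimated correlation, adjusted p = 0.0382). NRF2 targets rose in 23 of 29 and fell in 0, the same adjusted over the list alone, with a median of 1.07 (adjusted p = 0.0382 by camera with an estimated correlation). From 15 h to 24 h 2477 genes were called, 1352 higher and 1125 lower. Cd68 rose by 2.16 ± 0.14, Tnfrsf12a by 2.40 ± 0.26 and the chromatin protein gene Hmga1 by 2.27 ± 0.10, while Pdgfra (−3.00 ± 0.31) and Dlx2 (−2.62 ± 0.09) fell. GABAergic markers fell in 6 of 9 and rose in 0, the same adjusted over the list alone, with a median of −0.49 (camera, adjusted p = 0.0141 with an estimated correlation). Within chips the 15 h to 24 h count was 363 and 548 by the labels and 680 and 5044 by identical signals, where each chip holds a single array of 1 of the 2 times, assumed to vary like the others. From 8 h to 24 h 6090 genes were called, 3047 higher and 3043 lower, among them Anxa3 (4.92 ± 0.15) and Syt1 (−3.30 ± 0.25). Within chips the count from 8 h to 24 h was 3163 and 4032, by the labels.

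Across 11048 genes, which are not independent replicates, the log2 changes at 15 h and 24 h had a Pearson r of 0.857 and a Spearman rho of 0.819. Unchanged groups against the same controls gave a simulated r of 0.429. That r holds where no gene changes, so it is no baseline for changes as wide as at 15 h or 24 h. The covariance, which can be set beside its simulated value, was 0.314 against 0.0057. With the controls split into separate pairs r was 0.822 to 0.842. At both times 1998 genes were higher and 2201 lower, against 771 and 746 for independent lists, which leave out the shared controls. With split controls 1527 to 1579 were higher and 1741 to 1796 lower. In all, 71 genes were called in opposite directions. Of those 71, 48 were higher at 15 h and lower at 24 h, such as Dll1, a Notch ligand of neural progenitors (0.38 and −0.72), chosen after its values were seen. These opposite calls are from the quantile-normalised data only. Dlx2 and Sox9, among the 48, lost their 15 h calls under median scaling (0.22 and 0.26) and no scaling (0.13 and 0.17). Whether the other genes keep opposite calls under another scaling was not tested. The changes at 8 h had an r of −0.14 with those at 15 h and −0.04 with those at 24 h (Spearman −0.15 and −0.06). With split controls r was −0.30 to −0.08 and −0.18 to 0.01, so the sign of the second was not settled. The covariances were −0.013 and −0.0039, below the simulated 0.0057.

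Direction at 15 h and 24 h depended on the scaling between arrays. The median change of all genes moved from 0.02 to −0.16 under median scaling, −0.18 in the authors' values and −0.25 with no scaling at 15 h, and from 0.01 to −0.25, −0.24 and −0.39 at 24 h. The calls at 15 h split into 1409 higher and 4563 lower under median scaling, 1331 and 4469 in the authors' values, and 826 and 5169 with no scaling. At 24 h the splits were 1499 and 5383, 1555 and 5030, and 905 and 6545. From 8 h to 15 h they were 1485 and 4493, 1406 and 4524, and 1091 and 4664. From 15 h to 24 h they were 601 and 1218, 664 and 1114, and 408 and 1260, and from 8 h to 24 h 1529 and 5284, 1544 and 5014, and 1030 and 5903. Relative to the median of all genes under median scaling, NRF2 targets stood at 0.69 at 15 h and 0.95 at 24 h, and integrated stress response genes at 0.57 and 0.93. Lists of p53 targets, astrocyte, microglia and fibroblast markers, metal response and inflammation kept a median above 0 under every scaling at both times, and the heat shock list did so at 24 h. Its 15 h median of 0.22 turned to −0.05, −0.03 and −0.14, or 0.11 relative to all genes under median scaling. Fewer of their members were higher with no scaling at 24 h, at 18 higher and 3 lower for NRF2 targets, 19 and 6 for the integrated stress response, 6 and 5 for p53 targets, 5 and 8 for heat shock and 3 and 4 for astrocyte markers. Synapse, cytoskeleton, glutamatergic and GABAergic lists kept a median below 0, with synapse genes at −1.89 and −2.03 at 24 h under median and no scaling.

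**Figure D4:**
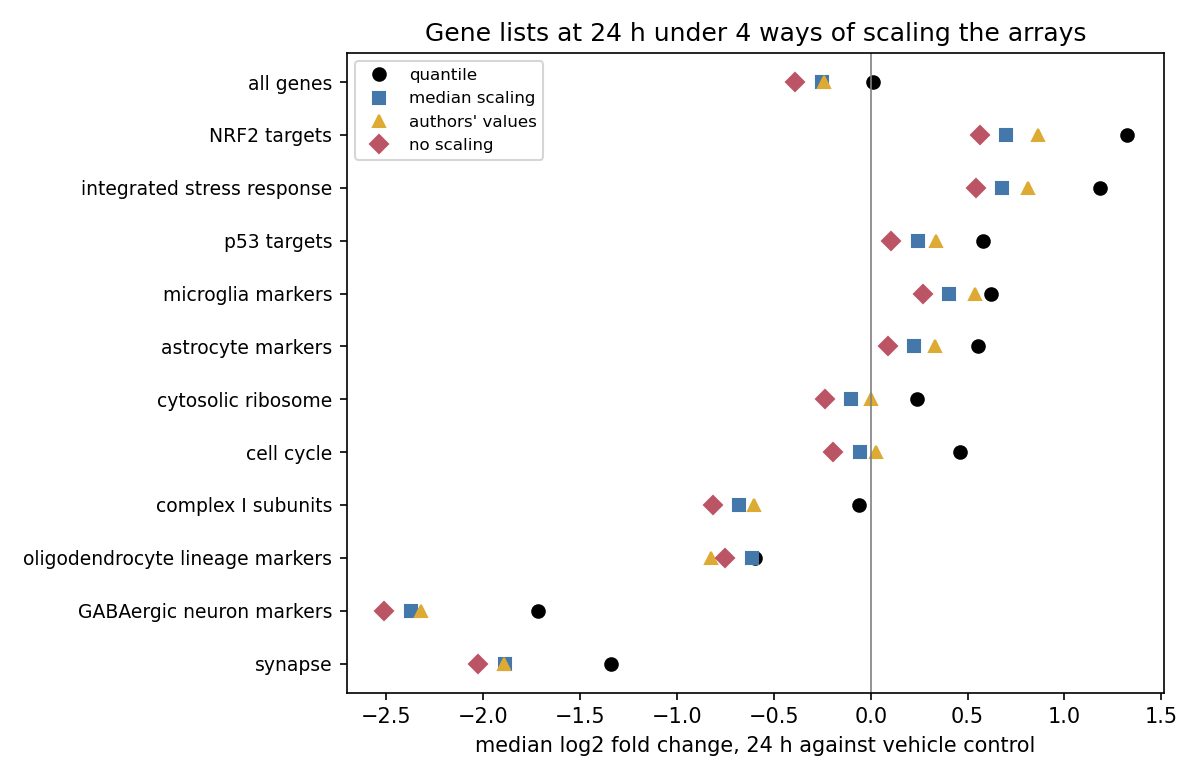
Median log2 change at 24 h of all genes and of a selection of the gene lists under quantile normalisation, median scaling, the authors' values and no scaling. NRF2 targets (1.32 to 0.56) stay above 0 and synapse genes (−1.34 to −2.03) below 0 in all 4. Cell cycle and ribosomal protein lists lie above 0 under quantile normalisation and below it with no scaling, where the median of all genes is −0.39. The glycolysis, hypoxia, unfolded protein response, cell death and immediate early lists, not drawn here, do the same.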

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

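The test of raw signals by brightness and both tests of cell markers were chosen after the results were seen, and the tests of the brightest probes, of 15 h replicate 1 and of other splits of the samples before.

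The mean raw signal fell from 371 in controls to 270 at 15 h and 235 at 24 h. One labelling factor for every transcript would lower probes of every brightness alike once they stand over background. The unscaled change at 24 h was −0.30, −0.66, −0.84 and −0.86 from the dimmest to the brightest of 4 equal groups of probes, and the brightest group differed from the next by −0.0188. This test replaced a first one, written before its result, which compared the brightest with the dimmest of 4 groups of the genes detected on every array. Its difference was −0.357 (SE 0.0321), beyond the limit of 0.3 set for it. It was set aside on the ground that its filter removes dim genes that fell. The values do not show that this lifted the dimmest group, which was at −0.501 with the filter and −0.30 without it. Without that filter the same contrast was −0.561, where dim genes lie near background. By its own limit the first test argues against one factor for every transcript. In the second test the brightest group and the next fell alike, but it was picked with the values in view. It therefore cannot overturn the first, and dim genes near background keep the question open. A smaller share of mRNA in the total RNA predicts the same and also stays open. A few probes taking more of the signal as the whole account are argued against, because the summed signal of the 100 brightest probes was itself 0.763 of that of the controls, although their share of all signal rose from 14.9% to 17.9%.

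At 24 h markers of neurons were lower and those of microglia (median relative to all genes 0.61), fibroblasts (0.91) and astrocytes (0.54) higher, while those of the oligodendrocyte lineage were lower (−0.61). A lower share of neurons and nothing else would raise the markers of every other type alike. The oligodendrocyte lineage and microglia medians differed by −1.21 (SE 0.518 from resampled members) and their means by −1.68 (SE 0.442). These errors treat the members of a list as independent and do not measure the spread between samples. The fall of the oligodendrocyte lineage list was not called by camera with an estimated correlation (adjusted p = 0.219), and its median with bounds was smaller. The difference leans against a lower share of neurons as the whole account but does not exclude it. For the microglia markers, scaling between arrays is argued against by their median of 0.271 with no scaling. Synapse genes were then at −2.03, but the median of all genes fell too, so that value weighs less. The test did not cover the other marker lists. Astrocyte and fibroblast medians also stayed above 0 with no scaling, but fewer astrocyte markers were called higher, so a part of scaling in their rise stays open. Loss of particular cells and a response within the remaining ones to rotenone both stay open, and may act together.

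Replicate 1 at 15 h differed from the other 15 h arrays by a median of 0.207 on the log2 scale, against 0.118 and 0.126 for the others, with 165 genes over 1 against 1 and 4, and it had the lowest detected share of the 13 arrays (50.2%). The highest of 3 correlations with the difference between matched chips in the other groups was 0.128, so no strong chip effect shared with those groups was seen. Replicate 1 is the only 15 h array on matched chip 2, so a chip effect at 15 h cannot be told apart from the array itself and stays open. Replicate 1 lay nearer the 24 h arrays on the first principal component (34.7 against 24.5 and 24.2) but away from them on the second. A later point of the same course as the whole account is argued against by a correlation of 0.101 with the 24 h difference, and an earlier point by −0.151 with the 8 h difference. Lower array or RNA quality was not tested and stays open, and the design names no biological difference for a single replicate.

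Other splits of the arrays into groups of the same sizes were tested. For 8 h against control 3 of 35 splits called as many as the real 48 genes, the highest other 459 (control 3 with 8 h replicates 1 and 3 against the rest), so chance could not be excluded for that count. A split that calls that many points to a structure of these samples beyond their groups. For 15 h 1 of 35 splits, the real one, reached 5541 genes, and the highest other was 2782. For 24 h 1 of 35 reached 6049, and the highest other was 3529. Chance is argued against for both counts but not excluded, as 1 of 35 is the smallest share these splits can give. The highest other split at both times set controls 1, 2 and 4 against control 3 and the treated arrays, so it holds much of the real contrast. Between times there are 10 splits, too few for a share under 0.05: 8 h to 15 h gave 5650 against a highest other of 1, 15 h to 24 h 2477 against 0, and 8 h to 24 h 6090 against 0, with 1 split each as large. For the list counts 9 of 35 splits reached the real 9 at 8 h (highest other 11), 3 of 35 the 15 at 15 h (15) and 2 of 35 the 17 at 24 h (17). Chance was therefore not excluded for any of the 3 list counts. At 15 h and 24 h the highest other split for the lists set controls 1, 2 and 3 against the rest, which is close to the real groups.

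Some lists and genes differed between times in a direct test of the difference, with medians or changes on opposite sides of the controls. The 8 h side of NRF2 targets, cytoskeleton genes and astrocyte markers was not called by camera with an estimated correlation (adjusted p = 0.197 for each). The cholesterol list was not called against control at 15 h or 24 h in the quantile-normalised data. Compared with 8 h, NRF2 targets were higher at 15 h and 24 h by medians of 1.07 and 1.33 (adjusted p = 0.0382 and 0.0204 with an estimated correlation), and cholesterol synthesis genes lower at −0.79 and −0.71 (0.0382 and 0.0342). Cytoskeleton genes were lower at −1.06 and −1.03 (0.0475 and 0.0428), and astrocyte markers higher at 15 h by 0.72 (0.0475). From 8 h to 15 h and to 24 h, Angptl4 was higher by 3.43 and 2.77, Ephx1 by 2.20 and 2.66 and Gsta4 by 2.88 and 3.83, while Dhcr7 stood at −1.27 and −1.42 and Fst at −2.011 and −2.002. Dlx2, Sox8 and Sox9 were higher by 1.32, 1.39 and 1.48 from 8 h to 15 h, and then stood at −2.62, −2.001 and −1.69 from 15 h to 24 h. The second probe of Dlx2 stayed below the controls at 8 h, 15 h and 24 h (−0.22, −0.05 and −0.52), and that of Angptl4 was at −0.28, 1.19 and 0.44. The 15 h calls of Dlx2 and Sox9 were lost under median scaling and no scaling.

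In 12 of 156 values tested 1 control array stood far from the other 3 by Dixon's ratio of its gap to the range of all 4, and chance gives about 1 in 20. For replicate 3, Acta2 was at 9.21 (others 9.86 to 9.97), Cox4i1 at 13.15 (13.34 to 13.37), Gch1 at 7.15 (6.50 to 6.59), Lss at 7.72 (7.02 to 7.13) and Rasgrf1 at 8.60 (9.62 to 9.65). For replicate 4, Atp5g2 was at 9.58 (9.32 to 9.36), Bok at 10.46 (10.19 to 10.23), Gdf15, detected on no control array, at 5.84 (6.05 to 6.06), Gfap at 8.09 (7.21 to 7.28) and Tuba1a at 10.68 (11.04 to 11.11). For replicate 1, Bbc3 was at 6.45 (6.24 to 6.27) and Fas at 6.30 (6.44 to 6.44).

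Probes without a symbol, which no comparison uses, held signal too. At 24 h 253 of the 489 such probes changed, 127 higher and 126 lower.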

How the results depend on the processing

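No scaling, neqc and the matched chips were chosen after seeing the data, as were median scaling, no scaling and neqc for the correlation. The 254 named gene results (159 genes) gave 7620 values under the alternatives, of which 95.9% kept direction and call. Of the others 246 lost the call, 21 gained one, 21 reversed and the rest changed sign without a call. The results at 8 h were less stable: 632 values kept direction and call, 119 lost the call, 13 gained one, 1 reversed and 15 changed sign without a call. Where a count moved by over 1.5 times or a direction turned, the cause was not tested.

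The 48 genes at 8 h were 3 within chip 1 and 0 within chip 2 (limma, 856 at an unadjusted p under 0.05), 17 with a replicate block, 2653 with array weights, 17 with only the groups compared, 3 and 1458 within matched chips 1 and 2, and 10 to 184 leaving out 1 array. The lowest came without 8 h replicates 1 or 3 and the highest without 15 h replicate 1. The 5541 at 15 h were 3626 within chip 1, 2541 within chip 2 and 3517 within matched chip 1, and the 6049 at 24 h were 3063 within chip 1 and 3709 within matched chip 1. From 8 h to 15 h the 5650 were 2562 within chip 2. From 15 h to 24 h the 2477 were 363 within chip 1, 548 within chip 2, 680 and 5044 within matched chips 1 and 2, and 4804 with array weights. From 8 h to 24 h the 6090 were 3163 within chip 1 and 4032 within chip 2. Fits within a chip hold fewer samples, with a single array in some arms, assumed to vary like the others. Whether equal replicate numbers mark a shared preparation is not given in the sources used here: 5 of 18 same-numbered pairs deviated together with r over 0.1 (mean 0.023), and the block moved no other gene count by over 1.5 times. Calls of lists went from 9 to 3 at 8 h, 15 to 0 at 15 h and 17 to 7 at 24 h with an estimated correlation, and to 4 at 8 h with fry. The correlation of 0.857 became 0.828 with controls split the first way, 0.889 under median scaling and 0.889 with no scaling.

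Reversed within matched chip 2 was Hmox1 at 8 h (0.54, from a single 8 h array). With no scaling at 15 h Atp5g2 (−0.052), Uqcrb (−0.077), Sel1l (−0.014), Diablo (−0.076) and Mt3 (−0.026) reversed, and at 24 h Rpl21 (−0.020), Rpl35a (−0.11) and Rps23 (−0.068). Under median scaling, the authors' values and no scaling Psmd4 was −0.060, −0.034 and −0.15 at 15 h and −0.30, −0.20 and −0.44 at 24 h, Ndufa2 −0.21, −0.10 and −0.34 and Psmc5 −0.16, −0.053 and −0.29 at 24 h. Signal over background limits dim genes.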

Other observations

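The 4 lists below, and the tests of histones, fatty acid oxidation and glutathione transferases, were chosen after the results were seen; the prediction for actin and adhesion genes was written before its result, but its list after values had been seen.

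Of 20 measured genes of a list of PPAR and fatty acid oxidation genes 3 were lower and 0 higher at 8 h, with a median of −0.33. Angptl4, already named among the falls at 8 h, was among the 3. At 15 h 18 were higher and 2 lower, with a median of 0.84, and of 0.31 with no scaling, or 0.56 relative to all genes. The mitochondrial carnitine transferase gene Cpt2 stood at −0.68, 1.21 and 0.90 at 8 h, 15 h and 24 h, Pdk4, which restrains pyruvate oxidation, at −0.55, 2.17 and 2.11, and the lipid droplet gene Plin2 at −0.34, 1.32 and 2.03. With an estimated correlation the adjusted p at 8 h was 0.0491 over the 4 added lists, but the list was put together after values of its genes had been seen, so whether they fall together stays open. The later rise was not called that way (adjusted p = 0.110 at 15 h and 0.217 at 24 h with an estimated correlation), and the 24 h median of 0.64 was 0.07 with no scaling, or 0.46 relative to all genes.

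Actin and adhesion genes under serum response factor were higher in 15 of 20 and lower in 1 at 24 h, with a median of 0.70, and of 0.36 with no scaling, or 0.75 relative to all genes. Flnc rose by 2.99, Myh9 by 2.35 and the matrix protein gene Ccn2 by 2.12, while Actb was at −0.28. With an estimated correlation the adjusted p was 0.0412 over the 4 added lists, but as the list was chosen with values in view, whether these genes rise together stays open. A shared regulator was not itself tested, and fibroblast markers rose too (Acta2 by 3.53 and Fn1 by 1.89), so a larger share of such cells stays open. Glutathione transferases and related genes were higher in 12 of 18 and lower in 2 at 24 h, with a median of 0.64, and of 0.08 with no scaling, or 0.47 relative to all genes. Gsta2 rose by 4.20 and the efflux pump gene Abcc4 by 2.35, but the list was not called with an estimated correlation (adjusted p = 0.101). Histone genes of the replication-dependent clusters were higher in 34 of 42 and lower in 1 at 15 h, with a median of 0.83. With no scaling that median was 0.38, or 0.63 relative to all genes. At 24 h 24 were higher and 3 lower, with a median of 0.45 that turned to −0.00 with no scaling, or 0.39 relative to all genes. That they rise together was left open (camera with an estimated correlation, adjusted p = 0.110 at 15 h and 0.277 at 24 h).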
